A study of Homo sapiens with 9 samples.

How the data were processed

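Messenger RNA was sequenced from 9 libraries of Huh7, an established human hepatocellular carcinoma cell line grown as a monolayer. Per the labels' protocols, the cells had been infected with lentivirus carrying a short hairpin RNA in the pLKO.1 vector, packaged in HEK293T cells, and were kept under puromycin to give stable pools. The hairpin was a control (shControl) or was directed at IMPDH1 (shIMPDH1) or IMPDH2 (shIMPDH2), with 3 libraries in each of the 3 groups. Hairpin sequences, and whether more than 1 hairpin was used per gene, are not given in the sources used here. The replicates are biological per the series text, but how the cultures of a group were kept apart is not stated, and the p-values measure only the spread between these samples.

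RNA was checked for integrity and libraries were made with a strand-specific kit that enriches polyadenylated RNA, per the labels' protocols. Trim Galore, cutadapt, STAR and featureCounts and the genome build hg38 are named, without versions, in the submitters' processing notes. The annotation release, the strand setting of the counting, the treatment of reads with several positions and any filter are not given in the sources used here. The authors deposited 1 table of raw counts per gene, with gene symbols as identifiers and 1 column per library. It held 58684 genes, and the deposited counts were whole numbers that had not been normalised. Of counts from 1 to 20, 41.3% were even, so there was no sign of read mates counted separately.

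A library's total ranged from 44560837 to 58370328 counts. In R 4.3.3, edgeR 4.0.16 was used with its default filter on low counts by group, which left 17396 genes holding 99.9% or more of each library's counts, and with TMM scaling. Levels are given as CPM, counts scaled to a common library size with the TMM factors, with the standard deviation (SD) over the 3 libraries of a group. At these depths 3 counts were worth 0.0514 to 0.0673 CPM. A single quasi-likelihood model with the group as its only term was fitted to all 9 libraries, and each of the 3 comparisons was a contrast of it. The common biological coefficient of variation was 0.0268. Every log2 fold change carries a standard error (SE) computed as its size divided by the square root of its F statistic. Each adjusted p of a gene is from this edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and a gene was called, or said to have risen or fallen, at an adjusted p under 0.05. With a spread this small, changes of a few percent pass that threshold, so fold sizes are given beside the counts of genes. Chance alone puts 3 libraries of a group wholly above or below 3 others for 10% of genes.

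The groups, the tests, 39 gene lists, the rule for naming genes and the alternatives were set before the data were examined. The lists cover nucleotide metabolism, ribosome production, cell cycle, stress responses, lipid metabolism, liver functions and markers of other cell types. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and p-values were adjusted over the 39 lists. The same test with an estimated correlation was run beside it, as was fry, whose p asks whether the genes of a list move on balance 1 way without comparing them with other genes. Counts of called members are given over all genes tested and, where they differ, as adjusted over the list alone. A list can share members with another. The list of epithelial-mesenchymal transition also holds EPCAM, an epithelial marker, so its rising and falling counts do not measure the transition itself.

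The rule for naming genes takes the measured members of the list of de novo purine synthesis, the 8 rising and 8 falling genes of largest change in each comparison with a mean log2 CPM of at least 2 and no overlap between the libraries of both groups, up to 4 members of smallest p in each called list, and the 6 genes changed most by both knockdowns in the same direction. Not every gene that the rule takes is named. Genes named outside it are said to have been chosen after their values were seen. Coordinates are 1-based positions on GRCh38, the assembly also called hg38, from GENCODE 29 and were matched by symbol; 37074 of the 58684 symbols had a transcript of that name and 816 more were matched through 1 older symbol.

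Because the strand setting of the counting is not known here, genes whose exons overlap those of a gene on the opposite strand are uncertain. Among named genes the shared part of the exon bases was 59.0% for BRF2, 37.0% for CCNE2, 23.2% for HEATR1, 19.4% for CP, 12.4% for VIM, 11.4% for TAGLN, 11.1% for SLC25A32 and 10.1% for NTAN1. AKR1C1, the histone genes, FTL and the ribosomal protein genes have near-identical relatives or pseudogenes, and their reads can be split among copies.

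Replicates were compared before averaging. The mean chi-square per gene between libraries of a group lay between 1.81 and 7.19, so no pair differed by as little as sampling noise. The pairs with shControl replicate 1 differed most in their group, at 5.91 and 7.19. The pairs with shIMPDH2 replicate 1 came to 3.91 and 4.02. Principal components of log2 CPM put the libraries of each group together, with 32.5% and 28.2% of the variance on the leading pair.

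The procedure was tested on simulated counts drawn from the real means and library sizes, with 200 of 17396 genes changed. For shIMPDH1 against shControl it called 32% of genes changed by 1.1 times, 64% at 1.2, 68% at 1.5 and 84% at 2, and 7.87% of its calls were unchanged genes. For shIMPDH2 against shControl the shares were 36%, 42%, 68% and 84%, with 9.77% of calls unchanged. For shIMPDH2 against shIMPDH1 they were 20%, 64%, 74% and 78%, with 4.76% of calls unchanged. A shifted gene list was recovered in each simulation. With so few genes changed, the adjustment over all genes was stricter than in the data, so these shares need not hold there.

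The alternatives were DESeq2 size factors or upper-quartile factors in place of TMM, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, a minimum fold of 1.5 in the test, a fit on the compared groups only, the replicate number as a block, and leaving out each library in turn. Unchanged groups against the same control libraries were simulated 20 times for the comparison of both knockdowns.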

Results

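IMPDH1 and IMPDH2 encode the isozymes of inosine monophosphate dehydrogenase, the enzyme that commits purine synthesis to guanine nucleotides. Polyadenylated RNA of Huh7 cells with a knockdown of either gene was compared with RNA of cells carrying a control hairpin, and the knockdowns were compared with each other, to see which transcripts differ when either isozyme is lowered. Each group had 3 libraries. All adjusted p-values of genes are from the edgeR model and all log2 fold changes are given with the later-named group as the reference.

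Both hairpins lowered their target. IMPDH1 (chromosome 7, positions 128392277 to 128410252, minus strand) was at 62.7 CPM (SD 0.199, n = 3) in shControl and 24.5 CPM (SD 0.881) in shIMPDH1, a log2 fold change of -1.36 (SE 0.040, adjusted p = 7.92e-20) or 2.56-fold lower. IMPDH2 (chromosome 3, positions 49024325 to 49029408, minus strand) was at 228 CPM (SD 1.97) in shControl and 110 CPM (SD 0.254) in shIMPDH2, a log2 fold change of -1.05 (SE 0.025, adjusted p = 4.26e-22) or 2.07-fold lower. The isozyme that was not targeted rose by less in each knockdown. IMPDH2 reached 274 CPM (SD 3.03) in shIMPDH1, a log2 fold change of 0.27 (SE 0.023, adjusted p = 3.49e-10). IMPDH1 reached 70.3 CPM (SD 3.52) in shIMPDH2, a log2 fold change of 0.17 (SE 0.035, adjusted p = 0.000486). In each case the libraries of the targeted group lay below all libraries of the other groups. IMPDH2 was the more abundant transcript of the pair in each group.

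**Figure D1:**
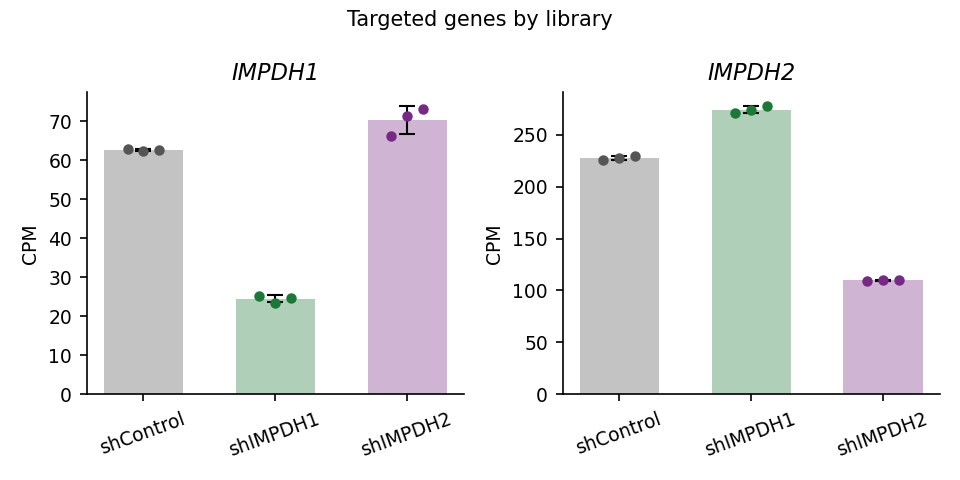
Level of IMPDH1 and IMPDH2 mRNA in counts per 1e6 (CPM) in shControl, shIMPDH1 and shIMPDH2, with bars for the mean of 3 libraries, points for libraries and error bars for the SD. IMPDH1 fell from 62.7 to 24.5 CPM in shIMPDH1 and IMPDH2 fell from 228 to 110 CPM in shIMPDH2.

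The other enzymes of de novo purine synthesis moved by small amounts. In shIMPDH1, PPAT (amidophosphoribosyltransferase, the committing step) rose with a log2 change of 0.12, GART with 0.16, PAICS with 0.08 and ADSS, which makes adenylosuccinate, with 0.18 (adjusted p = 5.19e-05). PFAS was at 0.00 (adjusted p = 0.917), ADSL at 0.06 (adjusted p = 0.0709), ATIC at 0.03 (adjusted p = 0.376) and GMPS, the enzyme after IMPDH, at 0.02 (adjusted p = 0.701). In shIMPDH2, PPAT rose with 0.17, PFAS fell by 0.15 and ADSS fell by 0.23, and GMPS was at 0.01 (adjusted p = 0.906). GART was at 0.05 (adjusted p = 0.190), PAICS at -0.01 (adjusted p = 0.872), ADSL at -0.01 (adjusted p = 0.892) and ATIC at 0.04 (adjusted p = 0.224). ADSSL1 was under 1 CPM in each group and was not called. Over the 11 measured members, with IMPDH1 and IMPDH2 among them, 5 rose and 1 fell in shIMPDH1, and 2 rose and 3 fell in shIMPDH2. Between the knockdowns 1 was higher and 6 were lower in shIMPDH2, and these counts were the same adjusted over the list alone. The list was not called by camera in shIMPDH1 (adjusted p = 0.196), where its median and mean differed in sign, in shIMPDH2 (adjusted p = 0.734) or between the knockdowns (adjusted p = 0.189). The call of PAICS in shIMPDH1 was lost without shControl replicate 1 (adjusted p = 0.0809) and without shIMPDH1 replicate 2 (adjusted p = 0.0501).

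In shIMPDH1 against shControl, 17 of 26 genes of epithelial-mesenchymal transition and 13 of 18 targets of YAP and TEAD fell, and 64 of 77 ribosomal protein genes rose. Camera called these lists, but not with an estimated correlation (adjusted p = 0.0636, 0.255 and 0.438). The calcium-binding protein gene S100A9 (chromosome 1, positions 153357854 to 153361027, plus strand) fell from 41.1 to 8.30 CPM, a log2 change of -2.31 (SE 0.059, n = 3 against 3, adjusted p = 4.81e-21). TAGLN, encoding the actin-binding protein transgelin (chromosome 11, positions 117199321 to 117204782, plus strand), fell from 51.0 to 12.4 CPM, a log2 change of -2.03 (SE 0.043, adjusted p = 2.50e-22). CPS1 (chromosome 2, positions 210477682 to 210679107, plus strand), the entry enzyme of the urea cycle, rose from 11.1 to 31.4 CPM, a log2 change of 1.50 (SE 0.053, adjusted p = 3.50e-18). DKK1, a secreted Wnt inhibitor, rose from 55.6 to 137 CPM, a log2 change of 1.30 (SE 0.035, adjusted p = 1.39e-20). DYNLRB1, a light chain of the dynein motor (chromosome 20, positions 34516409 to 34540958, plus strand), rose from 54.4 to 134 CPM, a log2 change of 1.30 (SE 0.029, adjusted p = 2.67e-22). Among the other genes of large change, PALM3 fell by 1.92, the metalloproteinase inhibitor TIMP2 by 1.92, the collagen COL12A1 by 1.81, the natriuretic peptide gene NPPB by 1.80 and ZNF114 by 1.76 on the log2 scale. BRINP3 rose with a log2 change of 1.84, the fibrillin FBN2 with 1.66, the stathmin STMN3 with 1.45, the mitochondrial folate enzyme ALDH1L2 with 1.40 and neurotensin, NTS, with 1.31. SE of these 10 genes lay between 0.055 and 0.127.

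In shIMPDH1, 64 of 77 measured genes of cytosolic ribosomal proteins rose, 1 fell and 12 were not called, with a median log2 change of 0.14 (camera adjusted p = 1.58e-11, adjusted p = 0.438 with an estimated correlation). RPL15 rose with 0.39, RPL13A with 0.29 and RPS3 with 0.25. The mean log2 CPM of this list was 8.94, 8.99 and 8.96 in the shControl libraries and 9.07, 9.11 and 9.14 in the shIMPDH1 libraries. Of 39 nucleolar and ribosome biogenesis genes, 24 rose, 1 fell and 14 were not called (median 0.11, camera adjusted p = 1.18e-05, adjusted p = 0.323 with an estimated correlation). Among them NOB1 rose with 0.32, BOP1 with 0.28, RRP1B with 0.24 and the nucleolar GTPase gene GNL3 with 0.23. In the machinery of RNA polymerases I and III, 14 of 27 genes rose, 3 fell and 10 were not called (median 0.10, camera adjusted p = 0.0197, adjusted p = 0.438 with an estimated correlation). POLR3D and TAF1C each rose with 0.38 and POLR3E with 0.35, and BRF2 fell by 0.50. This list's call was lost without shControl replicate 1 (camera adjusted p = 0.0714). With p adjusted over the list alone, 66 ribosomal protein genes rose and 1 fell, 26 nucleolar genes rose and 1 fell, and 14 polymerase genes rose and 3 fell.

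Of 26 genes of epithelial-mesenchymal transition, 17 fell, 2 rose and 7 were not called in shIMPDH1 (median -0.22, camera adjusted p = 3.27e-06, adjusted p = 0.0636 with an estimated correlation). Besides TAGLN, the matrix protein gene SPARC fell by 1.17, tropomyosin TPM1 by 0.68 and vimentin, VIM, by 0.53. Targets of YAP and TEAD fell too, with 13 of 18 down, 1 up and 4 not called (median -0.17, camera adjusted p = 1.00e-04, adjusted p = 0.255 with an estimated correlation), among them CYR61 by 0.93, ANKRD1 by 0.77, AMOTL2 by 0.41 and CTGF by 0.33. For G2 and mitosis, 24 of 38 genes fell, 3 rose and 11 were not called (median -0.09, camera adjusted p = 4.08e-04, adjusted p = 0.465 with an estimated correlation), and cyclin A, CCNA2, fell by 0.44, ANLN by 0.35, NUSAP1 by 0.31 and topoisomerase TOP2A by 0.28. For signalling by PI3K, mTOR and insulin, 16 of 27 genes fell, 3 rose and 8 were not called (median -0.16, camera adjusted p = 0.00234, adjusted p = 0.262 with an estimated correlation), with PIK3CB lower by 0.43, RPTOR by 0.37, IGF1R by 0.35 and TSC1 by 0.33. Of 22 hypoxia targets 12 fell, 1 rose and 9 were not called (median -0.15, camera adjusted p = 0.00984, adjusted p = 0.438 with an estimated correlation), and BNIP3L fell by 1.03, NDRG1 by 0.71, BNIP3 by 0.38 and the growth factor gene VEGFA by 0.37. A list of 7 endothelial and biliary markers had 3 that fell and 4 not called (median -0.40, camera adjusted p = 0.0229, adjusted p = 0.255 with an estimated correlation): KRT19 fell by 1.25, PECAM1 by 1.14 and EPCAM by 0.47, genes of a keratin and of adhesion molecules. These counts were the same adjusted over the list alone, except for 25 falling genes of G2 and mitosis and 17 of PI3K, mTOR and insulin signalling.

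In shIMPDH1, 14 of 19 genes of fatty acid synthesis and storage rose, 2 fell and 3 were not called (median 0.17, camera adjusted p = 1.09e-04, adjusted p = 0.0636 with an estimated correlation). The lipid droplet coat gene PLIN2 rose with 0.37, DGAT1 with 0.35, ELOVL5 with 0.32 and acetyl-CoA carboxylase, ACACA, with 0.29. Of 24 genes of cholesterol synthesis, 15 rose, 2 fell and 7 were not called (median 0.13, camera adjusted p = 6.96e-04, adjusted p = 0.262 with an estimated correlation), and MVD rose with 0.54, DHCR7 with 0.31 and INSIG1 with 0.30. Of 23 targets of NRF2, the regulator of antioxidant genes, 12 rose, 4 fell and 7 were not called (median 0.10, camera adjusted p = 0.0205, adjusted p = 0.262 with an estimated correlation). AKR1C1 rose with 1.06, NQO1 with 0.42 and the ferritin light chain FTL with 0.41. In serine and one-carbon metabolism 10 of 24 genes rose, 3 fell and 11 were not called (camera adjusted p = 0.0229, adjusted p = 0.255 with an estimated correlation), and besides ALDH1L2 the folate carrier SLC25A32 rose with 0.74 and AMT with 0.48, while GLDC fell by 0.35. In the last list 11 genes rose when adjusted over the list alone, and the other counts were the same.

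In all, 7552 of 17396 genes were called in shIMPDH1 against shControl, 3585 higher and 3967 lower. The median fold of the called genes was 1.19, and 527 differed by more than 2-fold, 188 higher and 339 lower. Of the called genes, 7256 had no overlap between the 3 libraries of each group, and over all genes tested 8990 had none, against a chance share of 10%. Camera called 13 of 39 lists, 7 higher and 6 lower, with 0 called by an estimated correlation (6 at an unadjusted p under 0.05) and 27 called by fry.

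In shIMPDH2 against shControl, 16 of 22 liver cancer and fetal liver markers fell, and 22 of 36 genes of proteins that hepatocytes secrete and 14 of 26 genes of epithelial-mesenchymal transition rose. These lists too were called by camera but not with an estimated correlation (adjusted p = 0.252, 0.659 and 0.299). NOX1, a superoxide-producing oxidase (chromosome X, positions 100843324 to 100874345, minus strand), fell from 10.8 to 0.910 CPM, a log2 change of -3.56 (SE 0.115, n = 3 against 3, adjusted p = 4.77e-19). The cadherin gene CDH17 (chromosome 8, positions 94127171 to 94217303, minus strand) fell from 81.3 to 19.97 CPM, a log2 change of -2.03 (SE 0.035, adjusted p = 7.19e-25). FGL1, a secreted hepatocyte protein (chromosome 8, positions 17864380 to 17910365, minus strand), rose from 183 to 461 CPM, a log2 change of 1.34 (SE 0.026, adjusted p = 5.49e-24). DYNLRB1 rose from 54.4 to 141 CPM here as well, a log2 change of 1.38 (SE 0.029, adjusted p = 5.55e-23). Among the other genes of large change, the guanylate cyclase receptor GUCY2C fell by 2.94, CPXM1 by 2.46, the amidase NTAN1 by 2.26, TIMP2 by 2.08, the mucin MUC13 by 2.07 and ZNF114 by 1.98 on the log2 scale. The kinase A inhibitor PKIB rose with a log2 change of 1.73, NGEF with 1.65, the glucosidase MGAM with 1.48, the ephrin receptor EPHA5 with 1.47, B4GALNT3 with 1.41 and NTS with 1.40. SE of these 12 genes lay between 0.057 and 0.121.

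Of 22 markers of liver cancer and fetal liver, 16 fell, 3 rose and 3 were not called in shIMPDH2 (median -0.16, camera adjusted p = 0.00104, adjusted p = 0.252 with an estimated correlation). EPCAM fell by 1.22, KRT19 by 1.15, the growth factor gene MDK by 0.68 and GOLM1 by 0.42. Of 36 proteins that hepatocytes secrete, 22 had higher mRNA, 7 had lower mRNA and 7 were not called (median 0.12, camera adjusted p = 0.00104, adjusted p = 0.659 with an estimated correlation). Plasminogen, PLG, rose with 0.79, ceruloplasmin, CP, with 0.61, the apolipoprotein APOA2 with 0.52 and fetuin, AHSG, with 0.48. Among 7 endothelial and biliary markers 5 fell and 2 were not called (median -0.77, camera adjusted p = 0.00798, adjusted p = 0.289 with an estimated correlation), with PECAM1 lower by 0.83 and the chloride channel CFTR by 0.76 beside EPCAM and KRT19. Of 26 genes of epithelial-mesenchymal transition, 14 rose, 5 fell and 7 were not called (median 0.17, camera adjusted p = 0.0140, adjusted p = 0.299 with an estimated correlation), and TAGLN rose with 1.07, THBS1 with 0.90 and VIM with 0.40. EPCAM, also on this last list, was among the 5 that fell. The secreted proteins had 23 rising genes when adjusted over the list alone, and the other counts were the same.

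Of 77 ribosomal protein genes 38 fell in shIMPDH2, 5 rose and 34 were not called (median -0.07, camera adjusted p = 0.00104, adjusted p = 0.758 with an estimated correlation). RPS12 fell by 0.35, RPL35 by 0.24 and RPLP2 by 0.22, and RPL15 rose with 0.22. The mean log2 CPM of the list was 8.87, 8.93 and 8.88 in the shIMPDH2 libraries, each below the lowest shControl library but by as little as 0.013. Of 13 mRNAs encoded by mitochondrial DNA 11 fell, 1 rose and 1 was not called (camera adjusted p = 0.0136, adjusted p = 0.659 with an estimated correlation), among them MT-ND3 by 0.48, MT-ND4 by 0.44, MT-ND4L by 0.41 and MT-CO3 by 0.36. Mitochondrial genes took 4.40% to 4.51% of counts in the shIMPDH2 libraries and 4.55%, 5.35% and 5.54% in shControl replicates 1, 2 and 3. Of 38 genes of G2 and mitosis, 22 fell, 4 rose and 12 were not called (median -0.10, camera adjusted p = 0.00617, adjusted p = 0.659 with an estimated correlation), and KIF23 fell by 0.49, TOP2A by 0.26, CDC20 by 0.23 and AURKB by 0.18. Adjusted over the list alone, 42 ribosomal protein genes fell and 5 rose, 24 genes of G2 and mitosis fell and 4 rose, and the mitochondrial counts were the same.

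Another 5 lists called in shIMPDH2 each lost the call when 1 library was left out. Of 42 genes of DNA replication 18 rose, 4 fell and 20 were not called (median 0.05, camera adjusted p = 0.0243, adjusted p = 0.659 with an estimated correlation), with CCNE2 higher by 0.43, RFC4 by 0.28 and E2F1 by 0.26, and RFC5 lower by 0.38; the call was lost without shControl replicate 1 (camera adjusted p = 0.0645). Of 23 glycolysis genes 13 fell, 3 rose and 7 were not called (median -0.08, camera adjusted p = 0.0287, adjusted p = 0.659 with an estimated correlation), and PFKFB3 fell by 0.59, the glucose transporter SLC2A1 by 0.36, and PKM and ALDOC each by 0.22. That call was lost without shControl replicate 2 (0.0571) or shIMPDH2 replicate 1 (0.0655). Of 24 genes of cholesterol synthesis 13 rose, 4 fell and 7 were not called (median 0.08, camera adjusted p = 0.0368, adjusted p = 0.659 with an estimated correlation), with MVD higher by 0.17 and TM7SF2 lower by 0.45. That call was lost without shControl replicate 1 (0.0597) or 3 (0.0589) and without shIMPDH2 replicate 1 (0.0547) or 2 (0.0511). Of 39 nucleolar and ribosome biogenesis genes 16 rose, 2 fell and 21 were not called (median 0.04, camera adjusted p = 0.0368, adjusted p = 0.659 with an estimated correlation), with BOP1 higher by 0.17, NOB1 by 0.15 and DDX21 by 0.14, and HEATR1 lower by 0.17. That call was lost without shControl replicate 1 (0.173) or shIMPDH2 replicate 1 (0.0645). Of 23 replication-dependent histone genes 6 rose, 1 fell and 16 were not called (median 0.34, camera adjusted p = 0.0485, adjusted p = 0.659 with an estimated correlation). HIST1H1C rose with 0.62, HIST1H2BK with 0.58, HIST1H2BD with 0.54 and HIST1H2AC with 0.51. The libraries enriched polyadenylated RNA, and how fully they sample the mRNAs of this list was not tested. The histone call was lost without shControl replicate 1 (0.0643) or 3 (0.0589) and without shIMPDH2 replicate 1 (0.0655) or 2 (0.0899). Adjusted over the list alone, 18 replication genes rose and 5 fell, 14 glycolysis genes fell, 14 cholesterol genes rose, 5 histone genes rose and the nucleolar counts were the same.

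In all, 6687 of 17396 genes were called in shIMPDH2 against shControl, 3229 higher and 3458 lower. The median fold of the called genes was 1.17, and 462 differed by more than 2-fold, 129 higher and 333 lower. Of the called genes, 6322 had no overlap between the libraries of the groups, and over all genes tested 8127 had none, against a chance share of 10%. Camera called 12 of 39 lists, 6 higher and 6 lower, with 0 called by an estimated correlation (3 at an unadjusted p under 0.05) and 28 called by fry.

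**Figure D2:**
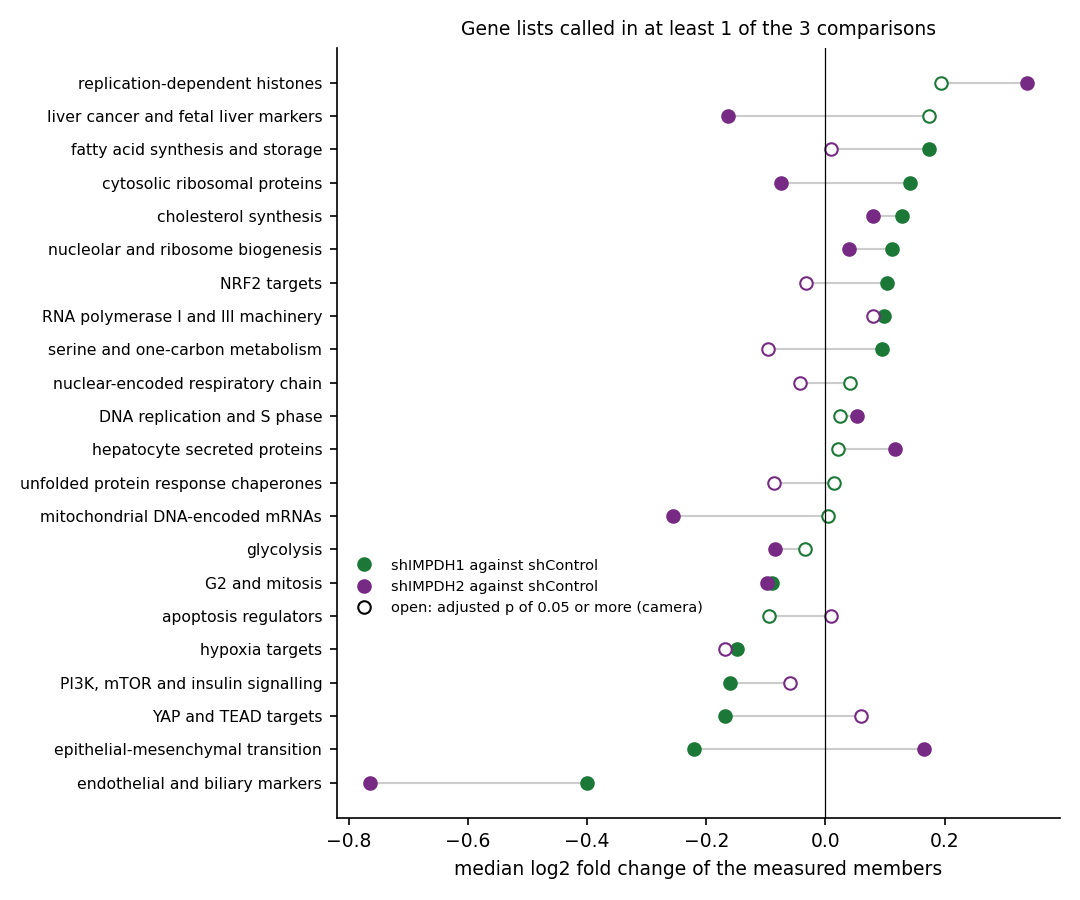
Median log2 fold change of the measured members (x axis) of each gene list that camera called in at least 1 of the 3 comparisons (y axis), with points for shIMPDH1 and shIMPDH2 against shControl, open where the list was not called. The median of the cytosolic ribosomal protein list was 0.14 in shIMPDH1 and -0.07 in shIMPDH2 against shControl.

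Between the knockdowns, 20 of 26 genes of epithelial-mesenchymal transition were higher and 71 of 77 ribosomal protein genes were lower in shIMPDH2 than in shIMPDH1. With an estimated correlation the call of the former held (adjusted p = 0.0286) and that of the latter did not (adjusted p = 0.511). TAGLN was at 12.4 CPM in shIMPDH1 and 107 CPM in shIMPDH2, a log2 change of 3.10 (SE 0.041, n = 3 against 3, adjusted p = 1.27e-27) or 8.57-fold higher in shIMPDH2. FGL1 was at 146 CPM in shIMPDH1 and 461 CPM in shIMPDH2, a log2 change of 1.66 (SE 0.026, adjusted p = 5.04e-26). STMN3 (chromosome 20, positions 63639705 to 63657682, minus strand) was at 33.6 CPM in shIMPDH1 and 7.02 CPM in shIMPDH2, a log2 change of -2.26 (SE 0.061, adjusted p = 5.51e-21). The natriuretic peptide gene NPPB was higher in shIMPDH2 with a log2 change of 2.74, the kinase ALPK3 with 2.12, PKIB with 2.06, COL12A1 and biglycan, BGN, each with 1.75 and MGAM with 1.73. Lower in shIMPDH2 were the estrogen sulfotransferase SULT1E1 by 2.26, GUCY2C by 2.26, NOX1 by 2.21, NTAN1 by 2.16, the actin-bundling fascin FSCN1 by 2.11, GALNT7 by 1.88 and COL26A1 by 1.83. SE of these 13 genes lay between 0.044 and 0.133. Chosen after their values were seen, the collagen gene COL1A1 had log2 changes of -1.22 in shIMPDH1 and 0.34 in shIMPDH2 against shControl, the myosin light chain MYL9 of -1.06 and 0.60, and calponin, CNN1, of -1.26 and 0.27.

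Of 77 ribosomal protein genes 71 were lower in shIMPDH2 than in shIMPDH1, 0 were higher and 6 were not called (median -0.23, camera adjusted p = 7.39e-17, adjusted p = 0.511 with an estimated correlation), among them RPLP1 by 0.36, RPS6 by 0.33 and RPSA by 0.32. Of 26 genes of epithelial-mesenchymal transition 20 were higher, 2 lower and 4 not called (median 0.41, camera adjusted p = 6.26e-09), including THBS1 with 1.46 and VIM with 0.93. This was the list whose call held with an estimated correlation (adjusted p = 0.0286), and no other list's call in any of the 3 comparisons did. Of 18 YAP and TEAD targets 14 were higher, 2 lower and 2 not called (median 0.29, camera adjusted p = 4.97e-06, adjusted p = 0.163 with an estimated correlation), with CYR61 at 1.40, ANKRD1 at 1.36, CTGF at 0.45 and AMOTL2 at 0.42. Of 22 liver cancer and fetal liver markers 15 were lower, 3 higher and 4 not called (median -0.30, camera adjusted p = 2.25e-04, adjusted p = 0.102 with an estimated correlation). The stem cell receptor LGR5 was lower by 1.52, MDK by 1.00, DLK1 by 0.82 and SPINK1 by 0.59. Against shControl, LGR5 rose with 1.23 in shIMPDH1 and fell by 0.29 in shIMPDH2. Adjusted over the list alone, 72 ribosomal protein genes were lower, 16 YAP and TEAD targets were higher, and 16 liver markers were lower and 4 higher.

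Further lists were called between the knockdowns, while those of cholesterol synthesis (camera adjusted p = 0.0939), glycolysis (0.392), the pentose phosphate pathway (0.166), purine salvage (0.501), purine catabolism (0.501), pyrimidine synthesis (0.421) and hepatocyte metabolism (0.392) were not. Of 19 genes of fatty acid synthesis and storage 12 were lower in shIMPDH2 than in shIMPDH1, 3 higher and 4 not called (camera adjusted p = 0.00701, adjusted p = 0.147 with an estimated correlation), with DGAT1 lower by 0.49, ELOVL6 by 0.38, PLIN2 by 0.28 and GPAM by 0.27. Of 24 genes of serine and one-carbon metabolism 15 were lower, 6 higher and 3 not called (camera adjusted p = 0.0197, adjusted p = 0.163 with an estimated correlation), and ALDH1L2 was lower by 1.05, methionine synthase, MTR, by 0.48 and PSAT1 by 0.27, with MAT1A higher by 1.08. Of 23 chaperone genes of the unfolded protein response 15 were lower, 3 higher and 5 not called (median -0.12, camera adjusted p = 0.00891, adjusted p = 0.511 with an estimated correlation), among them HERPUD1 by 0.38, SDF2L1 by 0.34 and CRELD2 by 0.30, while DNAJC3 was higher by 0.40. Of 13 mRNAs of mitochondrial DNA 9 were lower and 4 not called (median -0.27, camera adjusted p = 0.0123, adjusted p = 0.664 with an estimated correlation), with MT-ND3 and MT-ND4 each lower by 0.46. Of 63 genes of the nuclear-encoded respiratory chain 28 were lower, 6 higher and 29 not called (median -0.08, camera adjusted p = 0.0197, adjusted p = 0.729 with an estimated correlation), among them COX4I1 by 0.25, NDUFA4 by 0.23, UQCRH by 0.21 and ATP5A1 by 0.20, and this call was lost without shIMPDH1 replicate 3 (0.0788). Of 39 nucleolar and ribosome biogenesis genes 20 were lower, 5 higher and 14 not called (median -0.08, camera adjusted p = 0.0150, adjusted p = 0.557 with an estimated correlation), including HEATR1 by 0.27, RRS1 by 0.25, RRP1B by 0.22 and NOLC1 by 0.21. Of 27 apoptosis regulators 14 were higher, 3 lower and 10 not called (camera adjusted p = 0.0329, adjusted p = 0.363 with an estimated correlation), with XIAP at 0.35 and BCL2L1 and MCL1 each at 0.27. The last call was lost without shIMPDH1 replicate 2 (0.0589) or 3 (0.0520). Adjusted over the list alone, 11 mitochondrial mRNAs and 30 respiratory chain genes were lower and the other counts were the same.

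In all, 7648 of 17396 genes were called between the knockdowns, 3783 higher and 3865 lower in shIMPDH2. The median fold of the called genes was 1.19, and 576 differed by more than 2-fold, 283 higher and 293 lower. Of the called genes, 7333 had no overlap between the libraries of the groups, and over all genes tested 8954 had none, against a chance share of 10%. Camera called 11 of 39 lists, 3 higher and 8 lower, with 1 called by an estimated correlation (5 at an unadjusted p under 0.05) and 32 called by fry. The sign of the median and the mean differed for 3 lists in shIMPDH1, 8 in shIMPDH2 and 3 between the knockdowns, and none of these was called in that comparison. In each called list the median, the mean and the test had the same sign.

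Some genes moved the same way in both knockdowns against shControl. For such genes an effect of lowering either isozyme cannot be told apart from a trait of the control hairpin or control pool. TIMP2 (chromosome 17, positions 78852977 to 78925387, minus strand) fell from 10.4 CPM to 2.75 CPM in shIMPDH1 and 2.46 CPM in shIMPDH2, and the difference between the knockdowns was not called (log2 change -0.16, SE 0.105, adjusted p = 0.228). ZNF114 fell by 1.76 and 1.98 (difference -0.22, SE 0.107, adjusted p = 0.107) and PALM3 by 1.92 and 1.60 (difference 0.33, SE 0.150, adjusted p = 0.0803). CPXM1 and NOX1 fell in both but further in shIMPDH2, by 0.96 (adjusted p = 3.44e-07) and 2.21 (adjusted p = 1.66e-13). NTS rose in both (difference 0.09, SE 0.070, adjusted p = 0.347), and DYNLRB1 rose slightly further in shIMPDH2 (difference 0.08, SE 0.027, adjusted p = 0.0254). NTAN1 fell in shIMPDH2, was at -0.10 in shIMPDH1 (adjusted p = 0.246) and differed between them. In all, 3108 genes were called in the same direction in both comparisons with shControl, 1410 higher and 1698 lower, where independent lists of these sizes would share 665 and 789. A further 983 were called in opposite directions, 578 of them lower in shIMPDH1 and higher in shIMPDH2 and 405 the reverse, against 1449 for independent lists. Of those called in the same direction, 1770 were not called between the knockdowns. With both changes above 1.5-fold, 410 genes moved the same way and 46 in opposite ways.

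Both comparisons use the same 3 control libraries, which cannot be divided into separate sets of at least 2 for each knockdown, so part of the excess may come from the shared controls. In 20 simulations of unchanged groups against shared controls, the mean number of genes called in the same direction was 0.1. No gene was changed in these simulations, so almost none could be called. The 0.1 therefore cannot show what the shared controls add when 7552 and 6687 genes are called. The correlation of log2 changes across genes was 0.494 on average in the simulations (0.471 to 0.519), against 0.452 in the data. The covariance of the log2 changes was 0.0722 in the data and 0.0169 on average in the simulations (0.0161 to 0.0180). Genes are not independent replicates, and these correlations are across genes. With shIMPDH1 as the common reference 4327 genes were called in the same direction, and with shIMPDH2 3474, both more than the 3108 with shControl. A count this large was therefore not particular to shControl as the reference.

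**Figure D3:**
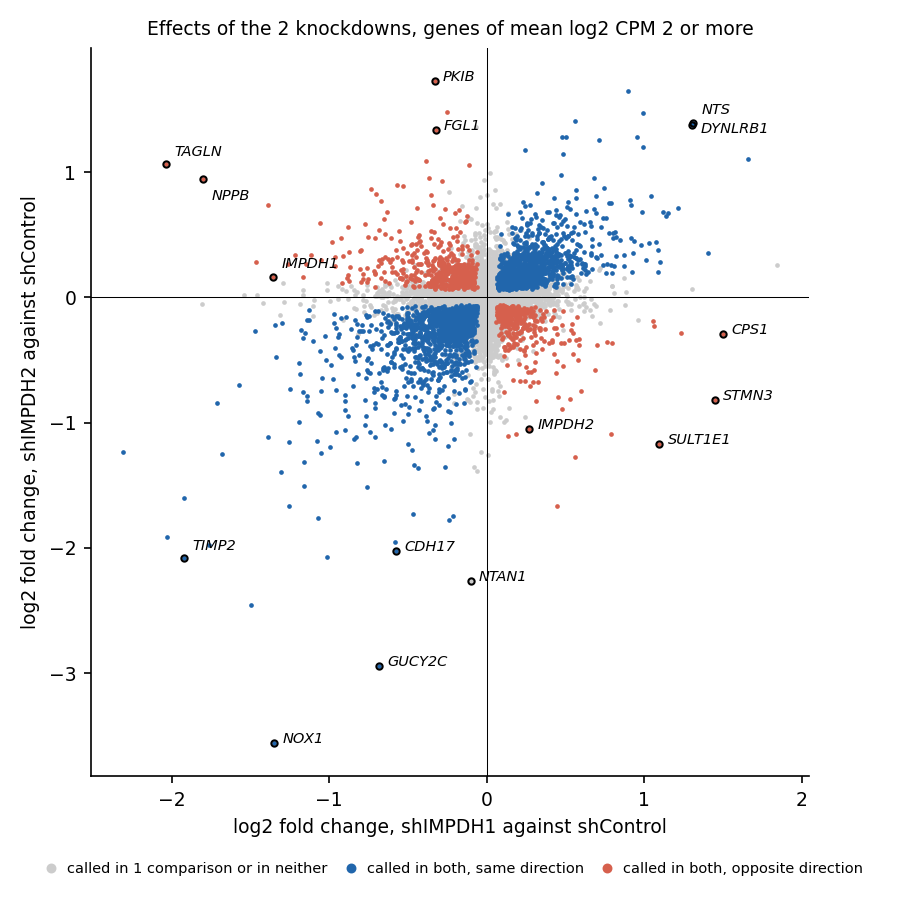
Log2 fold change of each gene with a mean log2 CPM of at least 2 in shIMPDH1 against shControl (x axis) and in shIMPDH2 against shControl (y axis), 1 point per gene, with genes called in both in the same direction, in both in opposite directions, and the rest in grey. Over all genes tested, 3108 were called in the same direction and 983 in opposite directions.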

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

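The alternatives were all set beforehand and none of these tests was chosen after the result was seen. The counts of called genes stayed within 1.5 times of the reported ones in each alternative except a test against a fold of 1.5, which called 457, 371 and 526 genes in shIMPDH1 against shControl, shIMPDH2 against shControl and shIMPDH2 against shIMPDH1, as its construction asks for larger changes. With the replicate number as a block 7726, 6848 and 7832 genes were called, and the DESeq2 Wald test called 6740, 5858 and 6870, of which 6726, 5843 and 6856 were also called by edgeR. The labels do not say that a replicate number marks a shared batch. Deviations from the group mean correlated at -0.006 to 0.247 in same-number pairs, with 2 of 9 pairs above 0.1. In 10 of 18 combinations of a library with another group, the library of its own number correlated best. Whether the numbers mark a shared batch therefore stays open. Lists were rerun with DESeq2 size factors as the only other scaling, and not with upper-quartile factors. Camera compares a list with the other genes, and a change of scaling moves all genes nearly alike. It could therefore hardly move the calls, so dependence on the scaling was not tested in earnest. The calls of lists did depend on the test. Camera with an estimated correlation called 0, 0 and 1 of 39 lists (6, 3 and 5 at an unadjusted p under 0.05), and fry, which tests a list alone, called 27, 28 and 32. In shIMPDH2 the call of the histone list was also lost with DESeq2 size factors (camera adjusted p = 0.0525), without the filter on low counts (0.336) and with the replicate block (0.0553), and those of the nucleolar list (0.0612) and of cholesterol synthesis (0.0565) with a fit on the 2 groups compared; the cause was not tested. Leaving out each library in turn gave 6511 to 7160, 5744 to 6228 and 6812 to 7235 called genes, 12 to 14, 8 to 13 and 9 to 12 called lists, and 2584 to 3032 genes called in the same direction by both knockdowns. The log2 change stayed between -1.38 and -1.33 for IMPDH1 in shIMPDH1, between -1.06 and -1.05 for IMPDH2 in shIMPDH2, between 0.26 and 0.28 for IMPDH2 in shIMPDH1 and between 0.14 and 0.21 for IMPDH1 in shIMPDH2, each with its call. The named genes were followed under the alternatives other than the test against a fold of 1.5. Of their 3010 values 2979 kept their direction and their side of the threshold, 16 changed sign, 11 lost a call and 4 gained one. Most of these genes were named for a large change or a small p in the same data, which favours stable calls. The changes of sign were all in purine enzymes that were not called. PFAS in shIMPDH1 was at -0.0043 without the filter and between -0.0105 and 0.0149 with a library left out. GMPS lay between -0.0114 and 0.0318 in shIMPDH1 with a library left out. In shIMPDH2, PAICS lay between -0.0365 and 0.0207, ADSL between -0.019 and 0.0086, and GMPS between -0.0117 and 0.0213 with a library left out, and GMPS was at -0.001 with upper-quartile factors. Between the knockdowns ATIC was at -0.0105 with upper-quartile factors and between -0.0023 and 0.0296 with a library left out, and GMPS lay between -0.0227 and 0.0012. These values lie near 0 and the cause was not tested. ADSL between the knockdowns, called at a log2 change of -0.07 (adjusted p = 0.0478), lost its call in 9 alternatives. Of simulated changes of 1.1-fold, 20% to 36% were called. The simulations changed 200 of 17396 genes by known folds, while 6687 to 7648 were called in the data. Adjustment over all genes is stricter with fewer changed genes, so these shares do not measure what this depth and spread resolve. Called changes below 1.1-fold stay uncertain.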

Other observations

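The test of ribosomal protein genes between shIMPDH1 and shIMPDH2 and that of a common ratio of intestinal genes were chosen only after the result was seen, and the contractile and intestinal gene lists were written after the genes of largest change were seen. The lists of targets of p53, ATF4 and NF-kB, of interferon-stimulated genes and of heat shock genes were not called by camera in either knockdown against shControl. Members of each were called, but over all genes tested 43.4% were called in shIMPDH1 and 38.4% in shIMPDH2 against shControl. Counts of called members therefore do not by themselves set these lists apart. Of 27 p53 targets 8 rose and 10 fell in shIMPDH1 (adjusted p = 0.823), and 9 rose and 6 fell in shIMPDH2 (adjusted p = 0.398). Chosen after their values were seen, as are all single genes named in this and the next paragraph except CPS1, the cell cycle inhibitor CDKN1A fell by 0.74 and 1.07 on the log2 scale and MDM2, the ligase that degrades p53, rose with 0.46 and 0.64. Of 31 targets of ATF4 11 rose and 7 fell in shIMPDH1 (adjusted p = 0.676), and 10 rose and 8 fell in shIMPDH2 (adjusted p = 0.862). TRIB3 rose with 0.50 in shIMPDH2 and was at -0.01 in shIMPDH1 (adjusted p = 0.787), and CHAC1 rose with 0.42 and 0.46. Of 31 interferon-stimulated genes 4 rose and 10 fell in shIMPDH1 (adjusted p = 0.386), and 7 rose and 6 fell in shIMPDH2 (adjusted p = 0.999). Of 24 targets of NF-kB 7 rose and 11 fell in shIMPDH1 (adjusted p = 0.397), and 9 rose and 9 fell in shIMPDH2 (adjusted p = 0.999). Of 20 heat shock genes 8 rose and 4 fell in shIMPDH1, where the list was not called, and 7 rose and 5 fell in shIMPDH2 (adjusted p = 0.778). As adjusted over the list alone, 8 targets of ATF4 fell, 5 interferon-stimulated genes rose and 9 heat shock genes rose and 5 fell in shIMPDH1, 10 targets of NF-kB and 8 heat shock genes rose in shIMPDH2, and the other counts were the same.

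Purine salvage had 9 of 23 genes that rose and 2 that fell in shIMPDH1 (adjusted p = 0.299), and 7 that rose and 2 that fell in shIMPDH2, where 5 fell as adjusted over the list alone and the list was not called either. APRT, which salvages adenine, rose with 0.31 in shIMPDH1, and HPRT1, which salvages guanine and hypoxanthine, was at 0.03 (adjusted p = 0.621) and at -0.10 in shIMPDH2 (adjusted p = 0.0510). DGUOK, a mitochondrial deoxyguanosine kinase, fell by 0.33 in shIMPDH2. Of 15 genes of purine catabolism 5 rose and 4 fell in shIMPDH1 (adjusted p = 0.753), and 1 rose and 3 fell in shIMPDH2 (adjusted p = 0.272). Of 20 genes of pyrimidine and deoxynucleotide synthesis 3 rose and 8 fell in shIMPDH1 (adjusted p = 0.190), 4 and 10 as adjusted over the list alone, and 5 rose and 5 fell in shIMPDH2 (adjusted p = 0.999). Among 36 transcription factors and metabolic genes of hepatocytes 13 rose and 10 fell in shIMPDH1 (adjusted p = 0.519), 13 and 11 as adjusted over the list alone, and 8 rose and 10 fell in shIMPDH2 (adjusted p = 0.662). Besides CPS1, the urea cycle genes ARG1 and ASS1 rose with 0.57 and 0.24 in shIMPDH1 and were at 0.10 (adjusted p = 0.268) and -0.06 (adjusted p = 0.253) in shIMPDH2. The bile acid receptor NR1H4 fell by 0.31 in shIMPDH1 and rose with 0.47 in shIMPDH2. Markers of immune cells, of fibroblasts and stellate cells and of HEK293T were not called. Of 6 immune markers 1 rose and 4 fell in shIMPDH1 (adjusted p = 0.190) and 1 rose and 1 fell in shIMPDH2 (adjusted p = 0.999). Of 7 fibroblast and stellate cell markers 1 rose and 2 fell in each (adjusted p = 0.676 and 0.768), and of 8 markers of HEK293T 2 rose and 3 fell in each (adjusted p = 0.995 in shIMPDH1), 3 and 3 as adjusted over the list alone.

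Of 77 ribosomal protein genes 64 rose in shIMPDH1 and 38 fell in shIMPDH2, and both calls of the list were lost with an estimated correlation (adjusted p = 0.438 and 0.758). Its call between the knockdowns was lost too (camera adjusted p = 0.511 with an estimated correlation). Transcript length and GC content were those of each gene's longest annotated transcript, which need not be the one expressed. After a trend with both was removed the median log2 change between the knockdowns was -0.229 (-0.227 before). Of 10000 lists matched for expression, 95% lay between -0.079 and 0. Those lists drew genes independently, while the estimated correlation within this list was 0.533, so that range is too narrow. The fitted trend thus did not remove the change, but a bias that follows the expressed transcripts stays open. Summed with their pseudogenes, the ribosomal protein genes changed by -0.217 on the log2 scale, against -0.2169 alone. This result was set beforehand to count against shared reads, but the CPM of the pseudogenes was 0.968% of that of the genes. So small a share could hardly move the sum. Reads discarded for having several positions would be in neither, so shared reads stay open. The smallest gap between groups in the list's mean log2 CPM, that between shControl and shIMPDH2, was 0.173 of the largest range within a group, so variation between libraries may account for the lower level in shIMPDH2 against shControl. The gap between the knockdowns was 1.88 times that range, so the spread between libraries of 1 group did not span it. That gap was tested only after the difference was seen. The range within groups also does not measure variation between separately made pools. Such variation stays open, as does the hypothesis of a change in ribosomal protein mRNA that differs between the isozymes or hairpins.

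Many contractile genes, led by TAGLN, were higher in shIMPDH2 than in shIMPDH1. A list of 31 target genes of SRF and contractile genes, written without the leading genes, had 27 higher and 1 lower, with a median of 0.24 (matched lists -0.104 to 0.037), but 2 of them, TPM1 and TPM2, are also on the list of epithelial-mesenchymal transition, and TPM1 is named in the report, so it is not fully independent; the other 29 had 25 higher and 1 lower with a median of 0.24, and against shControl it had 1 higher and 24 lower in shIMPDH1 (median -0.204) and 13 higher and 7 lower in shIMPDH2 (median 0.057, above matched lists at -0.082 to 0.038, but not called by camera). COL1A2, COL3A1, DCN and LUM together changed by -14.403 CPM from shIMPDH1 to shIMPDH2 while TAGLN rose by 94.21 CPM. This result was set beforehand to count against fibroblasts as the source. In shIMPDH2, COL1A2 was at 70.2, COL3A1 at 2.44, LUM at 1.04 and DCN at 0.0132 CPM. The sum is mostly COL1A2, whose own change can hide a rise of the others, so the sum does not decide on fibroblasts. At such levels COL3A1, LUM and DCN cannot have risen by as many CPM as TAGLN. COL1A1, left out as one of the leading genes, rose from 2.13 to 6.25 CPM. With the length and GC trend removed the median of the leading genes was 1.747 (1.751 before), and whether the isozyme, the hairpin or the selected pool makes the difference was not tested.

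Many genes of intestinal epithelium were lower in shIMPDH2, but not all, and the intestinal glucosidase MGAM, which is not on the list below, rose with 1.48. A list of 30 such genes, written without NOX1, GUCY2C, CDH17 and the others that had drawn attention, had 20 lower and 4 higher in shIMPDH2 than in shControl, with a median of -0.5 (matched lists -0.094 to 0.092), among them the transcription factor CDX2 by 1.06 and SI by 2.13, and 16 lower and 4 higher in shIMPDH1 (median -0.301); VIL1 was on both this and the contractile list. The 18 genes of at least 4 CPM in shControl had a median of -0.172 with 4 higher and 13 lower, a result set beforehand to count against cells of an intestinal line in the other cultures, but their median level of 31.2 CPM, against 15.3 CPM for the leading genes, would hide a small share of such cells, so this was not taken to exclude them. Loss of such cells as the whole cause would give 1 ratio of the fall in shIMPDH1 to that in shIMPDH2. Over 24 genes lower in shIMPDH2 the chi-square of a common ratio was 84.9 per degree of freedom with a fitted ratio of -0.205. DPP4 alone gave 847.7 of the total of 1953 and made the fitted ratio negative, although 17 of the 24 genes were lower in shIMPDH1 too. Without DPP4 the chi-square was 19.7 per degree of freedom with a ratio of 0.465, and for the leading genes alone 14.7 with 0.496. Among these CDH17 and GUCY2C had 0.437 and 0.436 and NOX1 and MUC13 both 0.663. This argues against such loss as the whole cause. A common ratio also fails if some of these genes changed in the Huh7 cells, and 7552 of 17396 genes were called in shIMPDH1. The test therefore says little about a part from such cells, which stays open, and an effect of the isozyme, the hairpin or the pool was not tested.

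Other groupings of the same libraries were tried for each count. For genes, 1 of the 10 splits of 6 libraries, the real one, gave as many calls in each comparison: 7552, 6687 and 7648 against 0 in the other splits by edgeR, which had 221 to 587, 288 to 674 and 279 to 519 genes at an unadjusted p under 0.05. For lists, 2 of the 10 splits gave as many calls in shIMPDH1 against shControl (13, with 13 as the highest other), 1 of the 10 in shIMPDH2 against shControl (12, highest other 7) and 1 of the 10 between the knockdowns (11, highest other 5). With 10 splits no share under 0.05 can be reached. For genes called in the same direction in both comparisons, 1 of 60 drawn splits of the 9 libraries gave as many as the 3108 of the real grouping. The highest other, 2587, had the shIMPDH1 libraries as the common reference and so kept 1 real group whole. A split that mixes the groups puts their differences inside its groups and so raises the spread, and the intact groups with shIMPDH1 or shIMPDH2 as the common reference, which were not among those drawn, gave 4327 and 3474. The splits are therefore not taken to exclude chance for this count.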
